A study of Arabidopsis thaliana with 12 samples.

How the data were processed

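Arabidopsis thaliana plants of the accession Col-0 and of the mutant sid2-1, which carries a lesion in an isochorismate synthase needed for most pathogen-induced salicylic acid, were grown in soil at 22 °C under a 12 h photoperiod for about 23 days. Per the labels, plants were either taken at 22 °C or kept for 3 weeks at 4 °C under a 12 h photoperiod and harvested 4 h after lights on. Plants of the cold groups were thus older than those of the warm groups, so that the cold contrasts include 3 weeks of age. Total RNA of the entire aerial part was extracted with a column kit, amplified, labelled with biotin and hybridized to 1 Affymetrix array per sample. The 12 arrays form 4 groups of 3 biological replicates, namely wild type at 22 °C, sid2-1 at 22 °C, wild type at 4 °C and sid2-1 at 4 °C. The titles of the wild-type arrays at 22 °C carry a bracketed mark that the labels do not explain.

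The deposited values are log2 signals made by the authors with GCRMA, a method that corrects the background from probe sequence, quantile-normalizes the arrays and summarises the probes of each probe set. Per the submitters' processing notes the tools were GCRMA and limma, with no versions given, and the set of arrays normalized together is not stated. The values run from 2.2 to 14.46 and are rounded to 2 decimals. The lowest value of 2.2 holds 14.8% of all values, and 1292 probe sets sit at it on all arrays. A fold against a group near that value, or at a low value that recurs exactly over arrays, depends on the background correction. Signal intensities carry no counts, so the number of arrays limits the precision.

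The table holds 22810 probe sets, of which 64 controls were left out and 22746 were tested. Probe sets were joined to genes through the platform table at hand, which lists 14016 of them. Of these, 13513 are annotated to 1 gene and 503 to several, and 8730 tested probe sets have no gene here. The reference gene table was joined by Entrez number and holds 13436 of the 13513, which measure 13286 loci. Genes are named by the symbol in that table, or by the locus where it gives none. ICS1 (the gene mutated in sid2-1), PR1, PR2, PR5, CBF1, CBF2, CBF3, FLC and VIN3 have no named probe set in this annotation, so no value is given for them, and the genotype labels could not be checked against the mutated gene.

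Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values. One linear model with a mean per group was fitted over all 12 arrays (lmFit, contrasts.fit and eBayes), with 8 residual degrees of freedom and 0.61 prior degrees of freedom. The 5 contrasts were the cold response of each genotype, sid2-1 against wild type at each temperature, and the difference of the cold responses, which is the interaction of genotype and temperature. The p values are two-sided and were adjusted by Benjamini-Hochberg over the 22746 probe sets of a contrast, with calls at an adjusted p under 0.05. The cold responses of both genotypes were also compared across probe sets by a slope and by correlations. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

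The contrasts, the tests, the rule for named genes, 22 gene lists and most alternatives were fixed before the data were examined. The rule took, in each contrast, genes with a probe set of 1 gene, an adjusted p under 0.05 and no overlap of the 3 and 3 values (in contrasts of a pair of groups), and named the 6 with the largest rise and the 6 with the largest fall. It further took up to 4 called members of each list with the largest change, or 2 members as values where none was called, and a fixed set of markers of which COR15A is measured. No overlap of 3 and 3 values arises for 10% of genes by chance. In the genotype contrast at 22 °C and in the interaction, fewer genes met the rule than it allows.

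Of the 287 genes in the 22 lists only 40 have a named probe set, and 4 lists reached the minimum of 4 members: CBF and COR cold response, flavonoid and anthocyanin synthesis, photosynthesis, and commonly used reference genes. Another 13 lists with 224 genes were therefore written from the annotation after its gene names were seen and before any difference between groups was computed: defence-associated genes, endoplasmic reticulum (ER) protein folding, nuclear photosynthesis, LEA and dehydration genes, starch and sugar transport, cell wall expansion, glucosinolate synthesis and transport, histone H2B and mitosis, heat shock, pollen and flower markers, root markers, plastid-encoded photosynthesis genes, and plastid-encoded transcription and translation genes. All 4 measured genes of the photosynthesis list are also in the nuclear photosynthesis list. The 17 lists were tested with camera on the same fit with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated from the data. Of all list calls, only that of the defence-associated genes in sid2-1 against wild type at 4 °C holds with an estimated correlation. Gene families of at least 8 measured members were formed from the letters of the symbols, and 28 of them were tested the same way.

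Whether the replicate numbers pair the samples was checked on the deviations of each array from its group mean. Across probe sets, same-numbered arrays of both genotypes correlated at 0.42, 0.28 and 0.47 at 22 °C and at 0.21, 0.23 and 0.25 at 4 °C. Between the temperatures the correlations were 0.00, 0.24 and 0.00 for wild type and 0.18, 0.03 and 0.07 for sid2-1. Unlike-numbered arrays of both genotypes correlated at -0.4 to 0.05 at 22 °C and at -0.36 to 0.13 at 4 °C, and unlike-numbered wild-type arrays between the temperatures reached 0.21. The numbers were thus taken to pair the genotypes within a temperature, less clearly at 4 °C. A replicate block was run as an alternative for all contrasts. A block within each temperature was added for the genotype contrasts after this was seen. Blocked results are given beside a genotype result where they change a call or move a value by over 1.5 times.

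The other alternatives were quantile normalization on top of the deposited values, median centring, a filter keeping probe sets with a mean over 4, eBayes with trend and robust settings, array weights, leaving out each array in turn, a fit of the 2 compared groups alone, a 2-fold threshold, and an adjusted p under 0.01. Other background corrections would need the raw array files, which were not used.

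The fit was tested on simulated data with 10 sets per contrast, each with 200 of 22746 probe sets changed. Changes were placed only on probe sets of middle mean signal, away from the lowest value, and the simulated arrays were not paired. The shares below therefore do not cover dim probe sets or paired arrays. In the contrasts of a pair of groups it recovered 29.0% to 30.4% of 2-fold, 78.4% to 81.8% of 4-fold and 91.2% to 95.0% of 8-fold changes. For the interaction these shares were 11.3%, 50.3% and 78.5%. False calls made up 6.3% to 7.4% of the calls, none of the recovered changes had the wrong sign, and a list of 20 genes shifted by 0.5 was called in 10 of 10 sets in every contrast. Unshifted lists were called in 1 of 10 sets in the cold contrast of wild type and in 0 of 10 sets in the other contrasts. A simulated list counted as called at an unadjusted camera p under 0.05. Simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.945. These shares therefore do not carry over to the real lists.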

Results

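Transcript levels were measured on 12 arrays in the aerial parts of soil-grown Arabidopsis, with 3 biological replicates each of wild type and sid2-1 at 22 °C and after 3 weeks at 4 °C. The arrays had nearly the same distribution, with median log2 signals of 4.39 to 4.47 and 13.05% to 15.96% of values at the lowest value. Replicates correlated across probe sets at 0.978 to 0.990. Over the 12422 probe sets with a mean above 4, the first principal component held 57.1% of the variance and parted the temperatures. On it the arrays at 22 °C lay between -51.8 and -37.4, the wild-type arrays at 4 °C at 54.0, 73.1 and 50.2, and the sid2-1 arrays at 4 °C at 30.7, 34.6 and 34.1. The second component held 13.4% and parted the genotypes at 4 °C, where wild-type replicate 2 stood apart at 47.8 from the 10.6 and 4.0 of the other wild-type arrays.

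**Figure D1:**
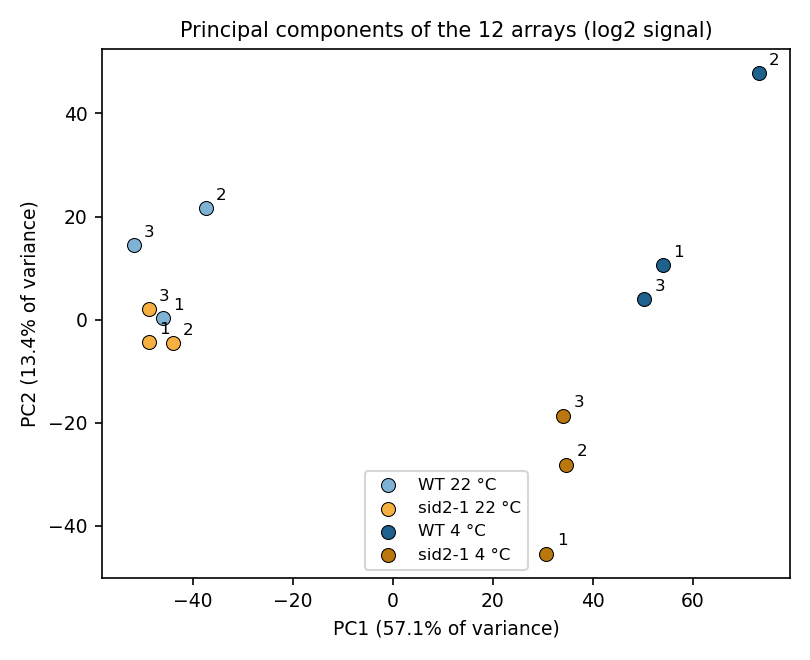
Principal components of the 12 arrays, with the scores on the first (horizontal, 57.1% of the variance) and the second component (vertical, 13.4%); each point is an array, coloured by group and numbered by replicate. The temperatures part on the first component, and the genotypes part at 4 °C on the second, with wild-type replicate 2 at 47.8.

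The first comparison asked which transcripts of wild-type shoots differed after 3 weeks at 4 °C from those of plants kept at 22 °C. LTI30 (AT3G50970), a dehydrin of cold-acclimated plants, rose 70.4-fold, a log2 change of 6.14 ± 0.45 (SE, n = 3 against 3). COR27 (AT5G42900) rose 26.4-fold, COR15B (AT2G42530) 11.9-fold, and COR15A (AT2G42540), a protectant of chloroplast membranes, 8.32-fold with a log2 change of 3.06 ± 0.66 (SE, n = 3 against 3). The largest rises under the rule were those of AT4G12490 (log2 change 7.77 ± 1.09, SE), the defensin-like LCR69 (6.19 ± 0.36), LTI30, the subtilase SBT3.3 (5.46 ± 0.64), AT2G43590 (5.13 ± 0.55) and CHI (AT2G43570), a putative chitinase and not the chalcone isomerase of the same symbol (5.08 ± 0.75). SBT3.3 stood near the lowest value at 22 °C, with a mean of 2.32 against 7.78 ± 1.59 (SD, n = 3) at 4 °C, so its fold depends on the background correction. The largest falls were those of AT1G73600 (log2 change -5.60 ± 0.46, SE), AT1G13650 (-5.59 ± 0.65), SWEET17 (-5.16 ± 0.48), a fructose transporter of the vacuole, the methionine sulfoxide reductase MSRB6 (-5.00 ± 0.65), AT3G28270 (-4.58 ± 0.79) and AT3G48460 (-4.45 ± 0.49). At 4 °C wild type had low values of 2.47, 2.47 and 3.54 for MSRB6 and of 2.71, 2.72 and 2.6 for AT1G13650. The sizes of these 2 falls therefore depend on the background correction.

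Of the 8 measured CBF and COR genes, 5 rose in wild type over all genes tested and 7 when adjusted over the list alone, with a median log2 change of 2.75 (adjusted p = 6.42e-07; adjusted p = 0.151 with an estimated correlation). Of the 29 defence-associated genes 18 rose, led by CHI, AT5G18470 (log2 change 4.96 ± 0.42, SE), AT5G55450 (4.38 ± 0.65) and AT3G18250 (4.33 ± 0.59). The median of that list was 1.30 (adjusted p = 2.51e-12; adjusted p = 0.151 with an estimated correlation). Of the 17 ER protein folding genes 8 rose, with a median of 0.70 (adjusted p = 6.42e-07; adjusted p = 0.151 with an estimated correlation). Among them, BZIP60, a transcription factor of the unfolded protein response, rose 3.81-fold and the calreticulin gene CRT1b 2.87-fold, beside AT1G29310 at 6.09-fold and AT5G07340 at 3.48-fold. The LEA and dehydration genes had 5 of 16 members that rose, with AT1G16850 at 28.8-fold, AT5G62360 at 17.4-fold, AT4G30650 at 5.72-fold and AT3G53990 at 3.63-fold, and 3 that fell (median log2 change 0.83, adjusted p = 0.0175; adjusted p = 0.393 with an estimated correlation). Nuclear photosynthesis genes shifted down with a median of -0.61, and 3 of 24 fell over all genes (adjusted p = 4.89e-06; adjusted p = 0.393 with an estimated correlation). These were PGRL1B of cyclic electron flow (log2 change -2.54 ± 0.23, SE), the antenna gene LHCB4.3 (-2.47 ± 0.39) and NdhN (-1.79 ± 0.28). In the shorter photosynthesis list none of the 4 members passed limma's test over all genes and 4 fell when adjusted over the list alone (median -0.40, adjusted p = 0.0175; adjusted p = 0.393 with an estimated correlation). The values closest to the threshold in it were those of LHCB4.2 (-0.81 ± 0.24) and RCA (-0.49 ± 0.14). Of the 6 glucosinolate genes 4 fell, namely UGT74B1 5.64-fold, AT2G31790 4.69-fold, BCAT4 4.57-fold and the transporter GTR1 2.24-fold (median -1.68, adjusted p = 0.00254; adjusted p = 0.250 with an estimated correlation).

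Plastid-encoded photosynthesis genes shifted down in wild type with a median log2 change of -0.37 over 43 members (adjusted p = 0.0175; adjusted p = 0.495 with an estimated correlation). Of these, psbC (-1.05 ± 0.27, SE) and psbF (-0.58 ± 0.15) fell, while rbcL, the large subunit of Rubisco, rose 3.31-fold. Among the 19 plastid-encoded transcription and translation genes, rps3 rose by a log2 change of 0.94 ± 0.18 and rpl22 by 0.81 ± 0.17 (list median 0.31, adjusted p = 0.0324; adjusted p = 0.495 with an estimated correlation). The other lists were not called in wild type. In starch and sugar transport, SWEET17 and SBE2.2 (-1.25 ± 0.32) fell and the tonoplast sugar importer TMT1 (1.68 ± 0.30) and SWEET1 (1.39 ± 0.25) rose among 15 members (list adjusted p = 0.400). In cell wall expansion, the expansins EXPA8 (-2.25 ± 0.57), EXPB3 (-2.22 ± 0.49) and EXPA4 (-1.98 ± 0.32) fell and EXLA1 (2.04 ± 0.55) rose among 20 members (list adjusted p = 0.400). The H2B gene HTB2 rose 6.26-fold alone among 11 genes of its list (adjusted p = 0.272), and the chaperone Hsp70-2 rose 4.46-fold alone among 8 heat shock genes (adjusted p = 0.207). Anthocyanin genes were not called, with DFR at -4.08 ± 2.15 and UF3GT at -3.35 ± 1.81 (list adjusted p = 0.272). Markers of other tissues were not called either, as pollen and flower markers had a median of 0.00 (adjusted p = 0.824) and root markers 0.01 (adjusted p = 0.229), with LPR2 as the single member that rose (2.27-fold). The reference genes had a median of 0.08 (adjusted p = 0.400), and 1 of the 4, AT4G34270, rose 1.38-fold.

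In all, limma called 2956 of 22746 probe sets in the cold response of wild type, 1549 higher and 1407 lower at 4 °C. Of them, 1951 changed at least 2-fold, 985 up and 966 down. The count was 1407 in a fit of the 2 wild-type groups alone, 1865 without wild-type replicate 2 at 4 °C and 1888 without wild-type replicate 3 at 22 °C. The cold plants were also older by the 3 weeks of treatment.

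**Figure D2:**
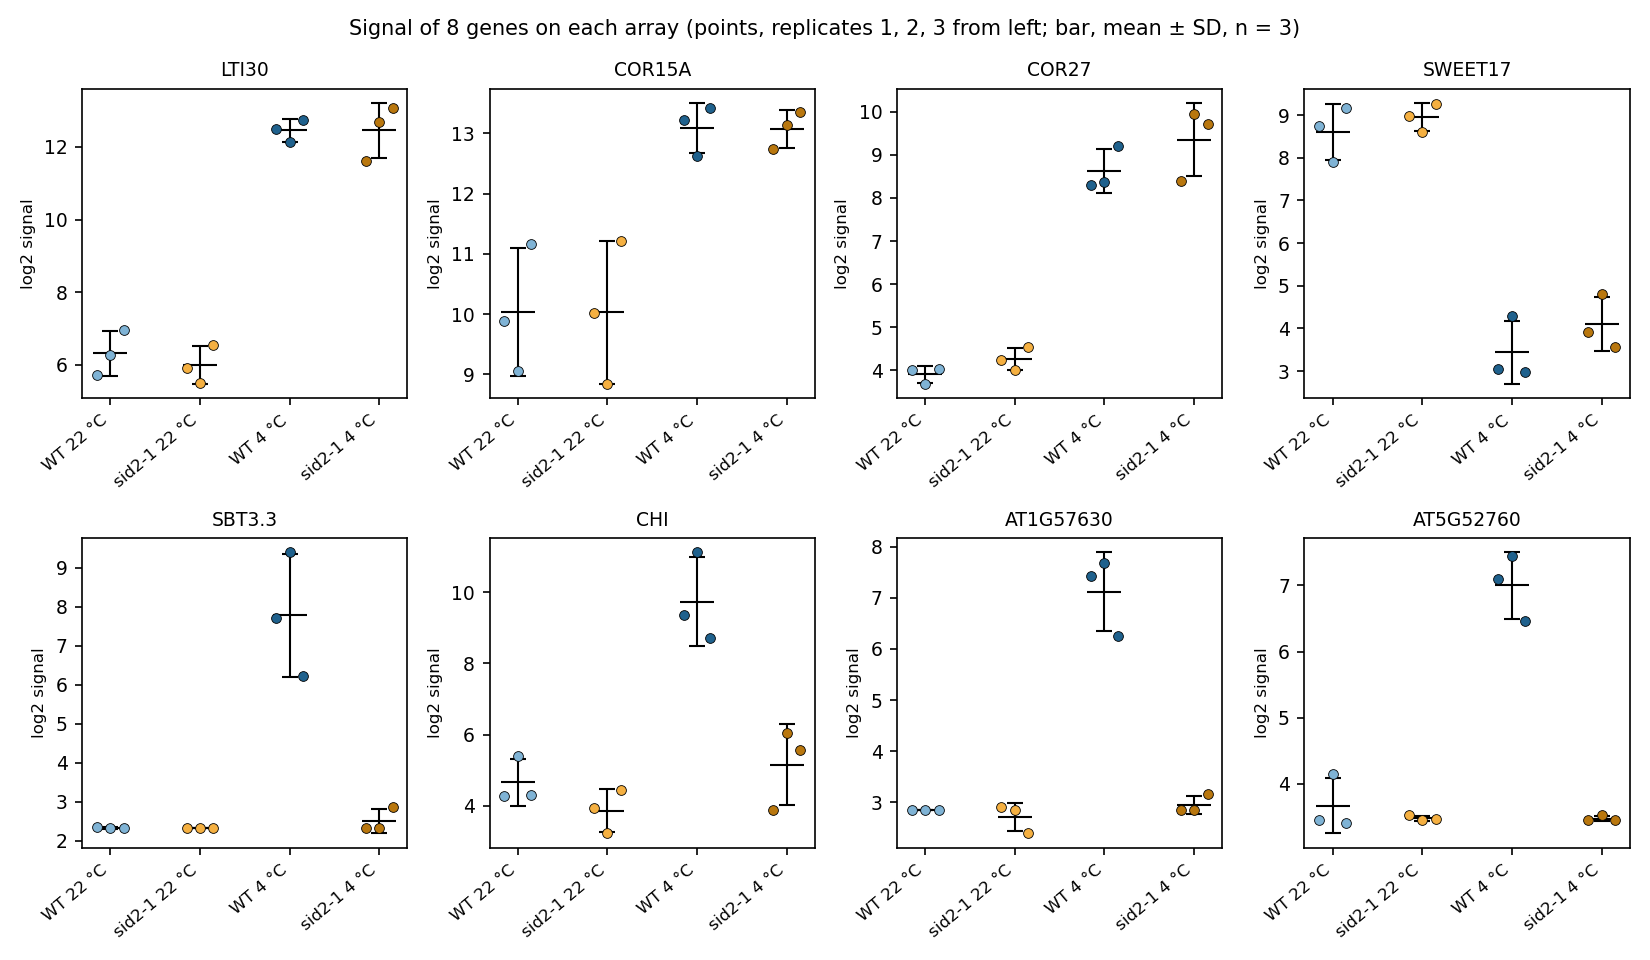
Log2 signal (vertical axis) of 8 genes in each of the 4 groups (horizontal axis); points are arrays, with replicates 1 to 3 from left to right, and bars give the mean ± SD (n = 3). LTI30, COR15A, COR27 and SWEET17 changed in the cold in both genotypes, while SBT3.3, CHI, AT1G57630 and AT5G52760 were high in wild type at 4 °C and lower in sid2-1 at 4 °C.

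The second comparison put the same question to sid2-1. LTI30 rose 87.6-fold in the mutant (log2 change 6.45 ± 0.45, SE, n = 3 against 3), COR27 34.0-fold, COR15B 12.0-fold and COR15A 8.28-fold (3.05 ± 0.66). AT4G12490 (6.29 ± 1.09), LCR69 (6.13 ± 0.36), the dehydration gene AT1G16850 (5.50 ± 0.54) and AT2G43590 (4.88 ± 0.55) were the other largest rises. The largest falls were those of AT1G13650 (-6.01 ± 0.65), MSRB6 (-5.87 ± 0.65), SWEET17 (-4.85 ± 0.48), CSLA01 (-4.28 ± 0.47), AT1G73600 (-4.03 ± 0.46) and AT2G32160 (-4.02 ± 0.43). CSLA01 stood at 3.13 on all 3 mutant arrays at 4 °C and MSRB6 at 3.03, 2.59 and 2.5, so their falls depend on the background correction. Of the 29 defence-associated genes, AT3G60420 (4.53-fold) and AT5G18470 (3.47-fold) rose in the mutant, and the list median was 0.01 (adjusted p = 0.401).

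Of the 8 CBF and COR genes, 6 rose in sid2-1 over all genes and 7 when adjusted over the list alone (median log2 change 2.73, adjusted p = 5.19e-08; adjusted p = 0.145 with an estimated correlation). ER protein folding genes shifted up with a median of 0.37 (adjusted p = 0.00473; adjusted p = 0.386 with an estimated correlation), and 3 of 17 rose, namely AT1G29310 (3.69-fold), AT5G07340 (2.61-fold) and AT2G34250 (1.61-fold). LEA and dehydration genes had 4 that rose, AT1G16850, AT4G30650 (8.02-fold), DI21 (4.90-fold) and AT3G53990 (3.61-fold), and 2 that fell (median 0.87, adjusted p = 0.00473; adjusted p = 0.386 with an estimated correlation). In nuclear photosynthesis LHCB4.3 (-2.29 ± 0.39) and PGRL1B (-2.21 ± 0.23) fell (list median -0.45, adjusted p = 4.83e-05; adjusted p = 0.413 with an estimated correlation). None of the 4 members of the shorter photosynthesis list passed limma's test over all genes and 3 fell when adjusted over the list alone (median -0.40, adjusted p = 0.0104; adjusted p = 0.386 with an estimated correlation); LHCB4.2 stood at -0.82 ± 0.24 and RCA at -0.55 ± 0.14. Of the glucosinolate genes, UGT74B1 fell by 1.81 on the log2 scale (list median -0.70, adjusted p = 0.0172; adjusted p = 0.386 with an estimated correlation). Plastid-encoded photosynthesis genes had a median of -0.29 (adjusted p = 0.00792; adjusted p = 0.666 with an estimated correlation), against which rbcL rose 3.75-fold. In plastid-encoded transcription and translation, rpl22 (1.79-fold) and rps3 (1.65-fold) rose (median 0.42, adjusted p = 0.00237; adjusted p = 0.413 with an estimated correlation).

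The remaining lists were not called in sid2-1. In starch and sugar transport (median 0.28, mean -0.07, adjusted p = 0.924), TMT1 (3.36-fold) and TMT2 (3.52-fold) rose and SWEET17 and SWEET16 (-1.68 ± 0.35) fell. In cell wall expansion (median 0.02, mean -0.12, adjusted p = 0.965) EXPA8 fell 5.67-fold and EXLA2 rose 1.81-fold from a value that recurred on 7 arrays (3.55), and HTB2 rose 2.92-fold in the H2B and mitosis list (adjusted p = 0.608). DFR stood at -2.32 ± 2.15 and UF3GT at -1.93 ± 1.81 in the anthocyanin list (adjusted p = 0.524), and BOB1 at 1.23 ± 0.51 and Hop1 at 0.25 ± 0.37 in the heat shock list (adjusted p = 0.605). LPR2 rose 1.71-fold among the root markers (adjusted p = 0.507) and AT4G34270 rose 1.40-fold among the reference genes (adjusted p = 0.144), while no pollen and flower marker was called (adjusted p = 0.965), with TUA1 at 0.33 ± 0.24. The fit called 1428 probe sets in sid2-1, 728 higher and 700 lower, of which 965 changed at least 2-fold. The count was 376 in a fit of the 2 mutant groups alone and 788 without sid2-1 replicate 1 at 22 °C, and 2243 with dim probe sets filtered out.

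The cold responses of both genotypes were then compared across probe sets. LTI30, COR15A, COR15B, COR27 and AT4G33980 were among the 565 probe sets called higher in the cold in both genotypes, and SWEET17, MSRB6 and PGRL1B among the 563 called lower in both. All 1128 probe sets called in both had the same sign, where independent calls would give 49.6 higher in both and 43.3 lower in both. Over the 3256 probe sets called in either genotype the slope of the sid2-1 response on the wild-type response was 0.695 ± 0.119 (jackknife SE over arrays), with a Pearson correlation of 0.880 and a Spearman correlation of 0.881 across probe sets, which are not independent replicates. The sign was the same in 95.8% of them. Selection favours the genotype in which a probe set was called. Over the probe sets called in wild type, the median ratio of sid2-1 to wild type was 0.694. Over those called in sid2-1, the median ratio of wild type to sid2-1 was 0.977, and 46.9% had the larger change in wild type. The 2 ratios were thus unlike, but no error over arrays was computed for them. Over the 4652 probe sets called for the mean response of both genotypes, a selection added after the data were seen, the slope was 0.737.

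**Figure D3:**
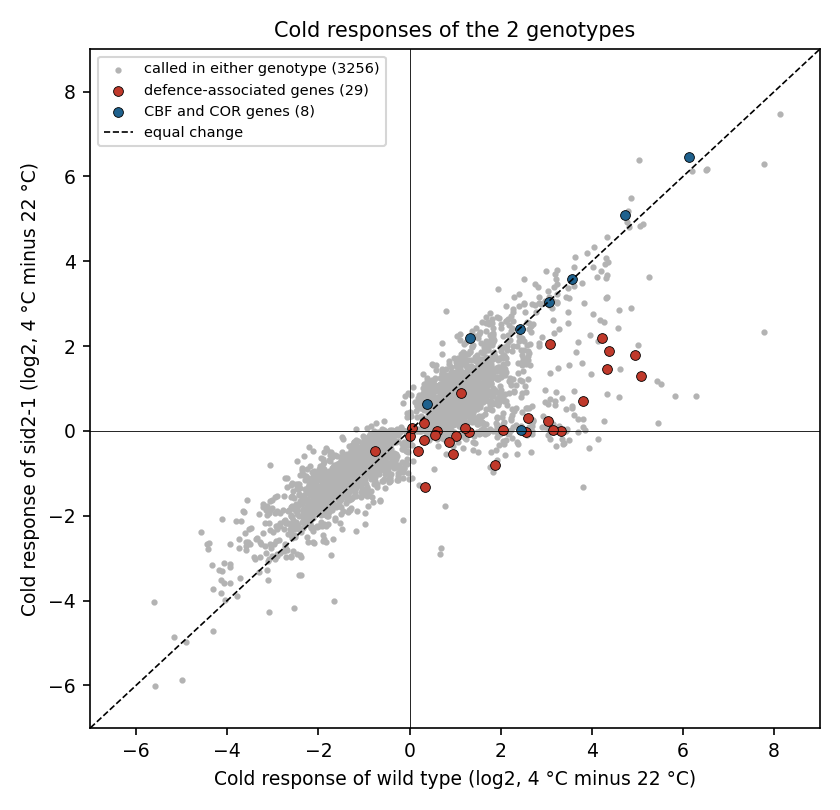
Cold response of sid2-1 (vertical axis, log2 change from 22 °C to 4 °C) against that of wild type (horizontal axis, same unit); grey points are the 3256 probe sets called in either genotype, red points the 29 defence-associated genes, blue points the 8 CBF and COR genes, and the dashed line marks equal change. Most CBF and COR genes lie near the line, whereas the defence-associated genes had a median log2 change of 1.30 in wild type and 0.01 in sid2-1.

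The third comparison asked how sid2-1 differed from wild type at 22 °C. AT2G40530 was the single gene called, with a log2 change of -0.51 ± 0.04 (SE, n = 3 against 3, adjusted p = 0.0191) between means of 2.78 in wild type and 2.27 in sid2-1, close to the lowest value. Among the 29 defence-associated genes none passed the test, but 22 had lower values in sid2-1, such as RING1 (-1.06 ± 0.47) and AT1G13470 (-1.0 ± 0.33), and the list shifted down with a median of -0.19 (adjusted p = 0.00806; adjusted p = 0.926 with an estimated correlation). The histone H2B and mitosis list shifted up with a median of 0.14 and no member called, as HTB2 stood at 1.05 ± 0.28 and HTB11 at 0.47 ± 0.11 (adjusted p = 0.00806; adjusted p = 0.230 with an estimated correlation). COR15A differed by -0.01 ± 0.66.

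The other 15 lists were not called at 22 °C and had no member past the test, with adjusted p from 0.288 for nuclear photosynthesis (median 0.09) to 0.914 for the CBF and COR genes (median 0.00). The anthocyanin list had a median of 0.73 (adjusted p = 0.632), with UF3GT at 0.89 ± 1.81 and DFR at 0.77 ± 2.15. At an unadjusted p under 0.05, limma gave 689 probe sets, where 0.05 of all tested is 1137. The 1292 probe sets at the lowest value on all arrays cannot reach that p, so 1137 slightly overstates what chance gives. They are too few to make up the gap to 689, which narrowed in the fits with a replicate block given next. AT2G40530 was not called with a replicate block (0 probe sets, 894 at an unadjusted p under 0.05), nor with a block within each temperature (0 probe sets, 1054), and the count reached 20 without wild-type replicate 3 and 15 without wild-type replicate 2 at 22 °C. The defence list had adjusted p = 0.560 without wild-type replicate 2, 0.0628 without sid2-1 replicate 1 and 0.214 without sid2-1 replicate 2 at 22 °C, and the H2B list 0.0649 with a block within each temperature, 0.0774 without sid2-1 replicate 1 and 0.107 without sid2-1 replicate 3 at 22 °C.

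The fourth comparison asked how the genotypes differed after 3 weeks at 4 °C. The subtilase gene SBT3.3 was 39.0-fold lower in sid2-1 (log2 change -5.29 ± 0.64, SE, n = 3 against 3), with a mean of 2.5 ± 0.31 (SD) in the mutant and 7.78 ± 1.59 in wild type. CHI was 23.9-fold lower (-4.58 ± 0.75), AT4G00700 18.4-fold (-4.20 ± 0.70), AT1G57630 18.0-fold (-4.17 ± 0.33), AT5G44570 14.3-fold (-3.84 ± 0.35) and AT1G13470 12.9-fold (-3.69 ± 0.33). In sid2-1 at 4 °C, AT5G44570 stood near the lowest value on all 3 arrays, with a mean of 2.25, and SBT3.3 on 2 of 3, with values of 2.31, 2.32 and 2.86, so their folds depend on the background correction. So do those of AT4G00700, at 2.36, 2.5 and 2.41 in sid2-1, and AT1G57630, whose 2.85 recurred on 6 of the 12 arrays. No gene named by a probe set of its own was called higher in sid2-1. COR15A differed by -0.01 ± 0.66 and was not called.

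Of the 29 defence-associated genes 9 fell over all genes tested and 20 when adjusted over the list alone, which is not a list fixed before the annotation was seen, and 28 had lower values in sid2-1. The median log2 change was -2.22 (adjusted p = 4.47e-30; adjusted p = 0.0463 with an estimated correlation), and -1.45 without wild-type replicate 2 at 4 °C. Beside CHI and AT1G13470, the largest falls in it were those of AT3G47480 (-3.68 ± 0.63, SE) and AT5G52760 (-3.53 ± 0.26), the latter against values of 3.45, 3.52 and 3.45 in sid2-1, where 3.45 recurred on 4 of the 12 arrays, so that its fall and the SE depend on the background correction. ER protein folding genes shifted down with a median of -0.52 and 15 of 17 lower values, of which AT2G34250 fell by 0.79 on the log2 scale (adjusted p = 2.52e-08; adjusted p = 0.131 with an estimated correlation). Nuclear photosynthesis genes shifted up with a median of 0.19 and no member called, with CHLI2 at 0.93 ± 0.40 and PAM68 at 0.84 ± 0.36 (adjusted p = 0.0115; adjusted p = 0.677 with an estimated correlation). That call ended without wild-type replicate 2 (adjusted p = 0.836) and without sid2-1 replicate 3 (adjusted p = 0.345) at 4 °C.

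**Figure D4:**
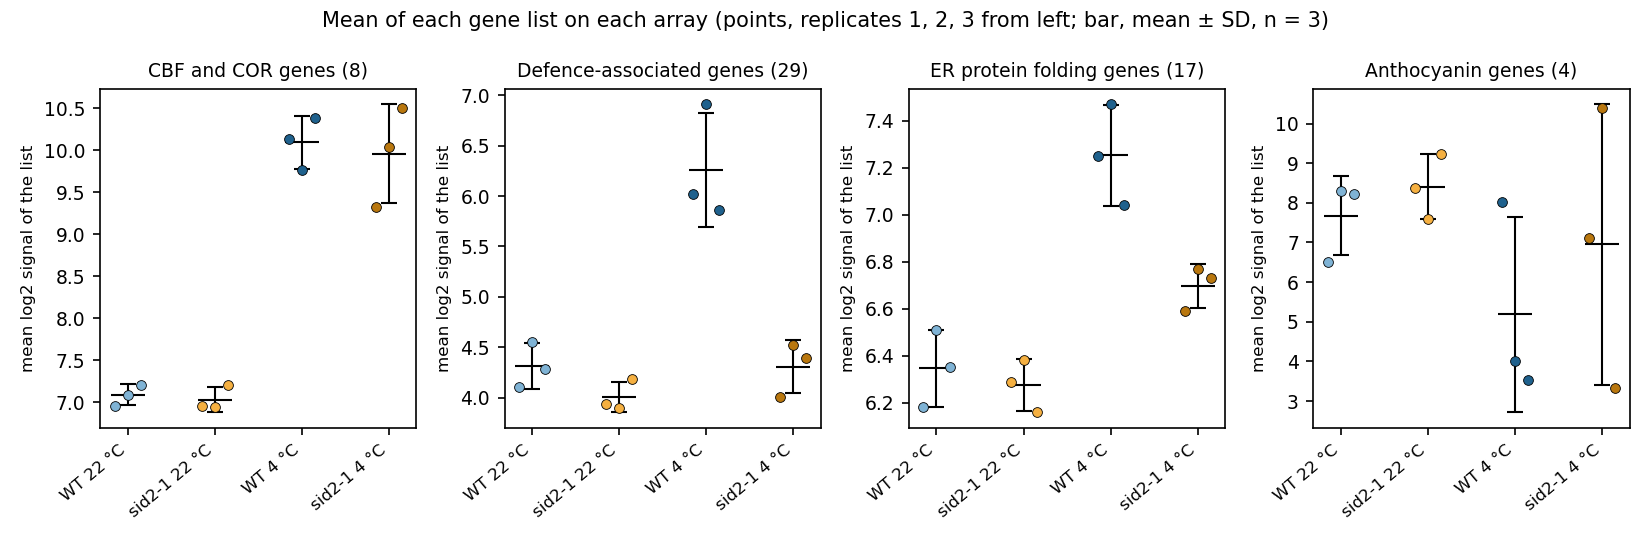
Mean log2 signal of each gene list on an array (vertical axis) by group (horizontal axis); points are arrays, with replicates 1 to 3 from left to right, and bars give the mean ± SD (n = 3). The defence-associated genes averaged 5.86 to 6.91 in wild type at 4 °C and 4.01 to 4.52 in sid2-1 at 4 °C, whereas the anthocyanin genes ranged from 3.34 to 10.4 over the sid2-1 arrays at 4 °C.

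The remaining 14 lists were not called at 4 °C. The CBF and COR genes had a median of 0.16 and a mean of -0.14 (adjusted p = 0.699), with COR27 at 0.73 ± 0.41 and the zinc-finger gene STZ, which pulled the mean down, at -2.82 ± 1.00. Hsp70-2 was 5.11-fold lower in sid2-1, alone among the 8 heat shock genes (list adjusted p = 0.247). Anthocyanin genes had a median of 2.1 (adjusted p = 0.306), with DFR at 2.53 ± 2.15 and UF3GT at 2.30 ± 1.81. The expansins EXPA15 (1.26 ± 0.42) and EXPA4 (1.22 ± 0.32) were the highest in the cell wall list (adjusted p = 0.109), and AT2G31790 (0.86 ± 0.31) and BCAT4 (0.80 ± 0.54) in the glucosinolate list (adjusted p = 0.115). The root marker LPR2 stood at -0.89 ± 0.17 and was not called (list adjusted p = 0.306), and the other lists had adjusted p from 0.247 to 0.879.

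Of the 140 probe sets called at 4 °C, 137 were lower and 3 higher in sid2-1, and 63 of the 137 are annotated to 1 gene. The share that was higher depended on single sid2-1 arrays at 4 °C, as 49 of 159 were higher without replicate 3, 29 of 124 without replicate 2 and 19 of 84 without replicate 1. Of the 137, 117 were also called higher in the cold in wild type, where independent lists would share 9.33. Both contrasts use the same wild-type arrays at 4 °C, so the overlap is no independent evidence: over all probe sets their correlation was -0.495 in simulated data with no effect and -0.54 as observed, with covariances of -0.031 and -0.176. The median cold response of the 137 was 2.08 in wild type and 0.00 in sid2-1. The 137 were selected on the same arrays at 4 °C, so a gap between these medians follows in part from the selection. A block within each temperature left 27 probe sets called, 16 of them among the 140, and of the 10 genes called above it left AT5G52760 (adjusted p = 0.0472). A block over all arrays ended the calls of CHI (adjusted p = 0.0538) and AT2G34250 (adjusted p = 0.0580). A fit of the 2 cold groups alone called 0 in limma (1504 at an unadjusted p under 0.05), the dim filter gave 213, and the count was 84 without sid2-1 replicate 1 at 4 °C, 86 without sid2-1 replicate 3 at 22 °C and 281 without wild-type replicate 3 at 4 °C.

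The last comparison tested whether the cold responses themselves differed between genotypes. AT1G57630 rose in the cold from a mean of 2.85 to 7.12 ± 0.77 (SD, n = 3) in wild type and stood at 2.71 and 2.95 in sid2-1, a difference of the responses of -4.03 ± 0.47 (SE). The other genes with a smaller response in sid2-1 were AT5G39670 (-3.43 ± 0.39), AT5G52760 (-3.34 ± 0.37), AT3G01830 (-3.19 ± 0.25), AT2G20142 (-2.81 ± 0.27) and the methionine sulfoxide reductase MSRB9 (-2.75 ± 0.34). Outside wild type at 4 °C, low values recurred exactly, 2.85 on 6 arrays for AT1G57630, 3.45 on 4 for AT5G52760, 2.99 on 3 for AT3G01830 and 3.02 on 3 for AT2G20142, and MSRB9 stood near the lowest value on 2 of 3 arrays a group, such as 2.27, 2.24 and 2.49 in sid2-1 at 4 °C. The differences and SEs of these 5 genes therefore depend on the background correction. AT2G40530 went the other way by 0.51 ± 0.06, close to the lowest value. The defence-associated genes had a median difference of -1.49 with 27 of 29 negative, AT5G52760 as the one member called over all genes and 15 called when adjusted over the list alone (adjusted p = 8.81e-22; adjusted p = 0.115 with an estimated correlation). ER protein folding genes had a median of -0.48 with 16 of 17 negative and no member called, as BZIP60 stood at -1.20 ± 0.38 and ATERDJ3B at -1.19 ± 0.60 (adjusted p = 6.67e-06; adjusted p = 0.289 with an estimated correlation).

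The other 15 lists showed no called difference of the responses and no called member, with adjusted p from 0.121 for the glucosinolate genes (median 0.69) to 0.955 for the shorter photosynthesis list (median -0.03, mean 0.01). The CBF and COR genes had a median of 0.14 and a mean of -0.08 (adjusted p = 0.774). COR15A differed by -0.01 ± 0.93, STZ by -2.43 ± 1.41 and Hsp70-2 by -2.23 ± 0.36 (adjusted p = 0.126), none of them called. The interaction called 14 probe sets, 13 with a lower and 1 with a higher response in sid2-1. At an unadjusted p under 0.05 it gave 928, where 0.05 of all tested is 1137. As at 22 °C, the probe sets at the lowest value are too few to make up this gap. With a replicate block limma gave 1260 at that unadjusted p. With a replicate block 3 were called, AT3G01830 being the single one of the named genes, with a block within each temperature 0 (1401 at an unadjusted p under 0.05 in limma), and with the dim filter 30. The count was 0 without wild-type replicate 1 at 22 °C, 6, 6 and 3 without sid2-1 replicates 1, 2 and 3 at 22 °C, 46 without wild-type replicate 2 at 4 °C and 70 without wild-type replicate 3 at 4 °C.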

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

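The test for swapped arrays, the regroupings that part every pair, the division of regroupings by the genotypes at 4 °C and the error of the slope without 1 array were chosen after results were seen. The other tests of this part were chosen before their results were seen.

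The interaction of genotype and temperature gave a difference between the cold responses of wild type and sid2-1 at 14 probe sets. Among the named genes the log2 differences were 0.51 for AT2G40530, -4.03 for AT1G57630, -3.43 for AT5G39670, -3.34 for AT5G52760, -3.19 for AT3G01830, -2.81 for AT2G20142 and -2.75 for MSRB9, all but that of AT5G39670 against low values that depend on the background correction. The median differences were -1.49 for the defence-associated genes and -0.48 for the ER protein folding genes. Of 100 regroupings of genotype within each temperature, 14 gave as many probe sets, the real one included, and another gave 70, so chance was not excluded for the count. Of these 14, 13 kept the real genotypes at 4 °C, the one with 70 included. They hold the difference seen there, so the share of 14 in 100 does not measure what chance alone gives. All 13 drawn regroupings of that kind gave as many, against 1 of the 87 that mixed the genotypes at 4 °C, with at most 14. Same-numbered arrays were taken to pair the genotypes within a temperature, and 88 of the 100 regroupings parted fewer pairs than the real grouping. Of all 32 regroupings that part every pair, 7 gave as many, with up to 40 in another; these 7 were among the 8 that kept the real genotypes at 4 °C, and the other 24 gave at most 3.

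The defence-associated genes were lower in sid2-1 at 4 °C, which did not rest on wild-type replicate 2, the array with the highest defence mean, since 127 of the 131 probe sets called without it were lower in sid2-1 and the list median was -1.45. It did not rest on the lowest value set by the background correction, since the 11 members with every group mean above 4 were all lower, with a median of -2.37 and an upper quartile of -1.70. A swap of 1 or 2 arrays of each genotype at 4 °C would have left arrays out of place, but the lowest wild-type array lay 1.33 above the highest sid2-1 array in the list mean, where the largest SD within a group was 0.57. An exchange of all 3 arrays would leave that gap and was not excluded. A candidate explanation is the loss of isochorismate synthase in sid2-1, a hypothesis that these arrays did not test, since the gene has no named probe set of its own here; other differences between the lines were not tested either.

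The slope of the sid2-1 cold response on that of wild type was 0.695 over the probe sets called in either genotype. Of those called in sid2-1, 46.9% had the larger change in wild type, with a median ratio of wild type to sid2-1 of 0.977. Over those called in wild type the median ratio of sid2-1 to wild type was 0.694. Without wild-type replicate 2 at 4 °C the slope was 0.772 ± 0.08 (jackknife SE over the other 11 arrays), against 0.695 with it. Selection of probe sets mostly called in wild type can lower this slope even where the responses are equal. Whether that array made a real shortfall therefore cannot be told from the slope. Selection on chance values of wild type cannot be told apart from a real difference, since 67.2% ± 13.4 (jackknife SE) of the probe sets called for the mean cold response had the larger change in wild type, within 2 SE of an even share. The 29 listed defence-associated genes are too few to make such a share, and none of them was called lower in the cold in either genotype. Among the 2262 probe sets that fell the share was 70.2% ± 17, and among the 2390 that rose 64.3% ± 13.2. Both lie within 2 SE of an even share, so a lean among the other genes cannot be told from chance. Unlisted defence-associated genes were not counted. With errors this wide, a weaker cold response in the mutant stays an open hypothesis.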

How the results depend on the processing

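The block within each temperature and the slope over the mean cold response were chosen after the data were seen. No call of a named gene reversed under any alternative run. Those called in every alternative fit that tested them were 30 of 49 in the cold response of wild type. In that of sid2-1 they were 16 of 36. They were 0 of 10 at 4 °C, 0 of 7 in the interaction and 0 of 1 at 22 °C. The 2-fold threshold and the adjusted p under 0.01 were not applied to named genes. The dim filter left some of the named calls untested, and the 90 that it tested all held. Among the named calls, quantile normalization ended 1, array weights 3, median centring 2 and the replicate block 17. The block within each temperature ended 17 of those between genotypes, the fit of 2 groups alone 46 and leaving out an array 12 to 28. No scaling moved the median log2 change of the probe sets with a mean above 4 by 0.1. The slope between the cold responses was 0.695 ± 0.119 (jackknife SE over arrays). It was 0.696 with the replicate block, 0.69 with quantile normalization, 0.693 with median centring and 0.716 with the dim filter. Over the probe sets called for the mean response it was 0.737, and it was not computed under the other fits and thresholds. Without 1 array it was 0.625 to 0.772. The SE is made from these last slopes, so they cannot test stability against it.

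The cold response of wild type gave 1407 probe sets with the 2 groups alone, where fewer arrays estimate the spread, 1951 with a 2-fold threshold, 1127 at an adjusted p under 0.01, and 1865 (without wild-type replicate 2 at 4 °C) to 2859 without 1 array, with 1888 without wild-type replicate 3 at 22 °C. That of sid2-1 gave 2243 with the dim filter, which tests fewer probe sets, 376 with the 2 groups alone, 423 at an adjusted p under 0.01, and 788 (without sid2-1 replicate 1 at 22 °C) to 1457 without 1 array. At 22 °C the single call became 0 with the replicate block (894 at an unadjusted p under 0.05 in limma), median centring (662), the dim filter (342), the block within each temperature (1054), the 2-fold threshold and an adjusted p under 0.01, 2 with the 2 groups alone, and 0 to 20 without 1 array. The 20 came without wild-type replicate 3 at 22 °C, 15 without its replicate 2, 8, 6 and 3 without sid2-1 replicates 2, 3 and 1 there.

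At 4 °C the 140 became 213 with the dim filter, 0 with the 2 groups alone (1504 at an unadjusted p under 0.05), 27 with the block within each temperature, 40 at an adjusted p under 0.01, and 84 (without sid2-1 replicate 1 at 4 °C) to 281 (without wild-type replicate 3 at 4 °C), with 86 without sid2-1 replicate 3 at 22 °C. Without sid2-1 replicate 3 at 4 °C, 49 of 159 were higher in sid2-1, and without its replicates 1 and 2 there 19 of 84 and 29 of 124, against 3 of 140. The interaction's 14 became 3 with the replicate block, 30 with the dim filter, 0 with the block within each temperature (1401), 0 at an adjusted p under 0.01, and 0 (without wild-type replicate 1 at 22 °C, 873) to 70 (without wild-type replicate 3 at 4 °C). Apart from the fits of 2 groups, the filter and the stricter thresholds, the cause was not tested.

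With an estimated correlation camera called 0 lists in the cold response of wild type (3 of 17 at an unadjusted p under 0.05), 0 in that of sid2-1 (1), 0 at 22 °C (1), 1 at 4 °C (2) and 0 in the interaction (2). With the block within each temperature, 1 list was called at 22 °C. Without 1 array, 5 to 9 lists were called in sid2-1 (5 without its replicate 3 at 4 °C), 0 to 2 at 22 °C (0 without sid2-1 replicate 1, 1 without wild-type replicate 2) and 2 to 5 at 4 °C (5 without wild-type replicate 1 or sid2-1 replicates 1 or 3). Probe sets near the lowest value of 2.2 limit what a fold can show, and other background corrections were not run.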

Other observations

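The genes below and the test of the lean at 22 °C were chosen after the values were seen, except for DFR and UF3GT, which the rule named.

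The anthocyanin genes DFR, UF3GT and AT4G14090 differed widely between arrays of the same group in the cold. DFR, an enzyme of anthocyanin synthesis, had log2 signals of 9.0, 3.2 and 2.9 in wild type and of 8.1, 11.3 and 3.4 in sid2-1 at 4 °C, with SDs of 3.42 and 3.95 (n = 3) against 1.22 and 0.96 at 22 °C. By residual SD it ranked 2 of all 22746 probe sets, AT4G14090 ranked 3, UF3GT 6, AT5MAT 17 and CHIL 23. The flavonol glycosyltransferases UGT78D1 and UGT78D2 ranked 478 and 144. These ranks pool all 4 groups, and the spread was not wider in the cold for every gene. In wild type the SD of AT5MAT was 0.77 at 4 °C and 0.78 at 22 °C, and that of UGT78D2 0.52 and 0.69. In sid2-1 those of AT5MAT were 2.85 and 0.96, and those of UGT78D2 1.55 and 0.83. On all of DFR, UF3GT and AT4G14090, sid2-1 replicate 2 had the highest value and wild-type replicate 3 the lowest in the cold. No cause of this spread was tested.

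The defensin genes PDF1.2 and PDF1.2b also varied. PDF1.2 stood at 4.0 in all wild-type arrays at 22 °C, at 9.1, 4.8 and 4.7 in sid2-1 at 22 °C, at 8.0, 8.5 and 6.4 in wild type at 4 °C, and at 8.3, 4.8 and 6.8 in sid2-1 at 4 °C. PDF1.2b followed with 9.4 in sid2-1 replicate 1 at 22 °C against 6.7 and 5.8 in the others. Neither was called in any contrast.

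WRKY53, the single measured gene of the senescence list, had means of 3.90 ± 0.68 (SD, n = 3) and 3.97 ± 0.48 in wild type and sid2-1 at 22 °C, and of 7.41 ± 1.00 and 3.76 ± 1.04 at 4 °C. Its cold response in wild type was 11.4-fold (adjusted p = 0.0104 in limma), and its difference between genotypes at 4 °C of -3.65 ± 0.65 (SE) was not called (adjusted p = 0.0583). UGT76B1, which conjugates salicylic acid and isoleucic acid, was called lower in sid2-1 at 4 °C (adjusted p = 0.0150 in limma), with a mean of 2.81 in wild type and the lowest value of 2.2 on every sid2-1 array, so no fold is given.

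Of the 28 gene families camera called 0 in any contrast, with the lowest adjusted p of 0.178 and 14 of the 140 tests at an unadjusted p under 0.05.

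The 137 probe sets lower in sid2-1 at 4 °C leaned the same way at 22 °C, where 76.6% of them were lower in sid2-1 by sign against 50.1% of all, with a median log2 change of -0.17. A lower defence state of the mutant already at 22 °C may be a source, but chance cannot be told apart from it: the real labels gave the highest share of the 20 labelings of the 6 arrays (1 of 20, the smallest share that 20 labelings can give), and the next highest reached 73.7%. These labelings leave the pairing of same-numbered arrays aside, and those that part every pair were not counted apart.

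Other splits of the samples were counted for each contrast of a pair of groups. For each of them 10 splits of 6 arrays are too few for a share under 0.05. In the cold response of wild type the real split gave 2956 probe sets and the highest other 1, and in that of sid2-1 1428 and 5. At 4 °C the real split gave 140 and the highest other 6, and at 22 °C 1 and 7, with 6 of 10 splits giving as many as the real one. Like the real one, 3 other splits part every pair of same-numbered arrays of the genotypes, and these gave 0, 3 and 2 probe sets at 4 °C and 0, 0 and 3 at 22 °C. The remaining 6 keep a pair of same-numbered arrays on each side.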
